A study of Escherichia coli with 4 samples.

How the data were processed

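Total RNA from Escherichia coli MG1655, a laboratory K-12 strain, was measured on 2-colour DNA microarrays. Per the labels' protocols, the cells grew without detectable oxygen in a 1 litre chemostat under a nitrogen flow of 0.2 litre per min, at a dilution rate of 0.2 per h. Glycerol at 54 mM was the limiting carbon and energy source, and fumarate at 50 mM served as electron acceptor. RNA was taken just before S-nitrosoglutathione (GSNO) was added to 200 µM and again after 5 min. There were 2 chemostat runs, and each run's pair of RNA samples was hybridised to 2 arrays, the second with the dyes exchanged, giving 4 arrays.

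The deposited values are 1 log ratio per probe and array, 4608 probes on each of the 4 arrays, with no missing value. How the authors made these ratios, used here as log2 ratios, from the scanned images before they were deposited is not given in the sources used here. The base of the log is not given in the sources used here: base 2 was taken as the usual one, and a natural log is not excluded, so every fold depends on that choice. Background correction, normalization within arrays and the direction of the ratio are likewise not given in the sources used here. Column medians were 0.06 and 0.01 for run 1 (GSNO in channel 2 and in channel 1) and 0.07 and -0.02 for run 2. The values hold no intensities, so signal over background is unknown, dim spots could not be filtered, and the number of arrays limits the precision. A deposited platform annotation gave 1 gene symbol for 4087 probes (4038 genes, of which 49 have 2 probes) and none for 521 probes (11.3%). By gene ID, 4086 of the symbols were matched to the RefSeq gene table of assembly ASM584v2, and 197 were updated to its names. The array's build is not given in the sources used here, so no coordinates are printed.

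The direction of the ratios was not settled by the rule fixed for it. The rule, written before the data were examined, read the correlation of an array with its dye swap across probes: below 0 the arrays with GSNO in channel 1 were to be multiplied by -1, above 0 nothing was to be turned, and an absolute value under 0.1 was to leave each orientation by itself. Pearson's r was -0.07 in run 1, which left the direction open, and -0.40 in run 2, which called for turning. The rule took for granted that dye effects are smaller than the response. The values were then used as deposited, read as already turned to GSNO over control, and the array and dye swap of each run were averaged. This reading departs from the fixed rule and was chosen after gene values and the call counts of 4 readings had been seen: as deposited (12 higher, 18 lower), channel 1 arrays multiplied by -1 (0 and 31), channel 2 arrays alone (4 and 9), and channel 1 arrays alone (0 and 0). It rests on neighbouring genes of operons. Across 833 pairs of neighbours that share the first 3 letters of the symbol and lie under 100 bp apart, r was 0.43 in the mean of the orientations, against 0.16 in 3203 other neighbour pairs. In the dye component, the difference between the orientations divided by 2, the values were 0.16 and 0.14. The sign that means higher after GSNO is only likely. Its basis, fixed beforehand, is that hmp, norV, norW, ytfE, hcp and hcr are known to be raised by nitric oxide, and all 6 had positive means. Every sign turns if this is wrong, and these 6 genes are no finding as to direction.

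The test was limma's moderated test (version 3.58.1, R 4.3.3; lmFit and eBayes) of the mean log2 ratio against 0 over the 2 run means, two-sided, with Benjamini-Hochberg adjustment over all 4608 probes and a threshold of 0.05. The 2 arrays of a run share their RNA and counted as 1 replicate, so n = 2 runs and SDs are between runs. The labels call the runs separate chemostat runs and say nothing more of their independence, so p-values concern only these 2. The moderated test takes each probe's spread mostly from all probes (prior degrees of freedom 10.5, against 1 of its own). A printed SD is thus not the spread behind its p-value: a gapA probe had an SD of 0.0051 and a standard error of 0.19. Nor does the SD show how far a run's 2 arrays differed. The run numbers pair each array with its dye swap, because both carry RNA of the same culture.

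For 24 gene lists written before the data were examined, camera with a preset correlation of 0.01 compared each list's members with all other probes, adjusted over the 24 lists. Camera with an estimated correlation and fry were run beside it. Counts "adjusted over the list alone" use the same limma p-values and are not adjusted over the 24 lists. Some lists share members, and a gene can pass in the smaller list and not in the larger. One such gene is carA, which passed in the arginine list and not in the purine and pyrimidine list. The genes named are the 12 highest and 12 lowest among those past the test with the same sign on all 4 arrays, filled up with the next values where fewer passed; the 6 genes above; and up to 4 members of each list with the largest absolute mean, plus all of its called members where these are 6 or fewer. Unnamed probes are not named. Other genes given below were chosen after their values were seen.

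The scripts were tested on simulated data. In 20 simulated sets of 4608 probes for this comparison, with 200 probes changed, 82.7% of changes of 1 log2 unit and 99.95% of those of 2 log2 units were recovered. Of the calls, 8.88% on average were false (0 to 18.75% per set), above the nominal 5%. The simulated sets had 1 residual degree of freedom per probe, like the data, and whether that is the cause was not tested. Unlike the data, the 2 simulated arrays of a run shared the same error, with no error of single arrays. Their dye effect was identical in both runs and was removed by averaging, whereas the dye components of the real runs correlated at 0.43. Spreads were drawn from the prior fitted to these data. The recovered and false shares thus need not hold for the real arrays. A list of 20 genes shifted by 0.5 log2 was found in 20 of 20 sets and an unshifted one in 0. Both counts used camera's unadjusted p under 0.05. Errors of the simulated probes were independent, so the 0 says nothing about false finds in lists of correlated genes. With an estimated correlation the shifted list was found in 0 of 20 sets (lowest p = 0.0827), as that form has 1 residual degree of freedom here.

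Alternatives fixed before the data were examined were a random or fixed replicate block on the 4 arrays, a dye term with the arrays as independent or with the fixed block, robust eBayes, treat, another threshold, other centring and scaling, averaging of a gene's probes, each dye orientation alone, each run alone, other fold limits, and for lists an estimated correlation, cameraPR and runs of neighbouring members that share the first 3 letters of the symbol counted once. Intensity trend and a missing-value filter had nothing to act on. Readings added after seeing the data were the 4 arrays as independent without a dye term, named probes alone, channel 1 arrays multiplied by -1, each array left out in turn, list members with the same first 3 letters counted once wherever they lie, and the nitric oxide list without the 6 genes that set the direction.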

Results

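The arrays compared E. coli cells 5 min after 200 µM GSNO, a nitrosothiol that serves as a source of nitric oxide and nitrosates thiols, with the same culture just before the addition. Cells were at steady state without oxygen, on glycerol with fumarate. There were 4 arrays from 2 chemostat runs: 2 with GSNO RNA in channel 2 and 2, the dye swaps, with it in channel 1. Ratios are given as GSNO over control, as mean log2 ratio ± SD between the 2 runs (n = 2). This direction is only likely. It was read from 6 genes known to be raised by nitric oxide (hmp, norV, norW, ytfE, hcp and hcr), whose means were all positive in the values as deposited. Only norV, norW and hcp of them passed the test, and hmp and hcr were below 0 in run 1.

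norV, norW and hcp of the nitric oxide response, metB, metR and metF of methionine synthesis and feoC and exbB of iron uptake were among the genes that rose. gatA, gatZ and gatY of galactitol uptake and breakdown, the ferritin gene ftnA and the ribosomal protein gene rpmG were among those that fell. In all, 12 of 4608 probes rose and 18 fell (limma, Benjamini-Hochberg adjusted). The largest increase was that of norV, which encodes the flavorubredoxin that reduces nitric oxide without oxygen, at 4.41 ± 1.31 (21.3-fold, adjusted p = 6.84e-05). An unnamed probe followed at 3.86 ± 0.76 (14.5-fold, adjusted p = 2.39e-05). Both values moved with single run 2 arrays: without the one with GSNO in channel 1, norV was at 5.81 (56.3-fold) and the probe at 4.75, and without the other at 3.01 (8.05-fold) and 2.98, neither past the test (limma, adjusted p from 0.0962 to 0.232). Without 1 of the run 1 arrays the probe was at 3.24 or 4.49. Next came metB of methionine synthesis at 2.54 ± 0.57 (5.81-fold, adjusted p = 0.000264) and hcp, the hybrid cluster protein, at 1.83 ± 0.25 (3.55-fold, adjusted p = 0.00131). The largest decrease was that of yobF, a small protein gene, which fell by 2.00 ± 0.47 (adjusted p = 0.00131).

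The other named genes that rose were feoC of ferrous iron uptake at 1.64 ± 0.52, metR, the activator of methionine genes, at 1.60 ± 0.35, and norW, the reductase that serves NorV, at 1.49 ± 0.31. Also higher were exbB, part of the energy supply of iron-siderophore uptake, at 1.33 ± 0.82, metF at 1.29 ± 0.56, the aminotransferase gene ybdL at 1.27 ± 0.14, nrdH, a glutaredoxin-like protein that serves a ribonucleotide reductase, at 1.21 ± 0.49, and copA, the copper exporter, at 1.12 ± 0.12. Their adjusted p-values ran from 0.00480 for metR to 0.0467 for exbB. Among the other named genes above 0 on all 4 arrays, the highest 2, exbD at 1.03 ± 0.45 and ilvC at 0.91 ± 0.39, did not pass (adjusted p = 0.0602 and 0.0816). norW was below 0 on 1 of the 4 arrays, that of run 2 with GSNO in channel 1, and stood at 2.28 without it and at 0.70 without the other run 2 array, and the other named genes that rose were above 0 on all 4.

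Among the genes that fell were ftnA, the iron storage ferritin, at -1.70 ± 1.02, borD, a lipoprotein gene, at -1.55 ± 0.53, and pheL, the leader peptide of phenylalanine synthesis, at -1.48 ± 0.97. Of the galactitol genes, gatA was at -1.54 ± 0.11, gatZ at -1.23 ± 0.13 and gatY at -1.08 ± 0.13, while the second gatY probe, at -0.82 ± 0.13, did not pass. Both probes of gapA, the glycolytic glyceraldehyde-3-phosphate dehydrogenase, fell, at -1.40 ± 0.53 and -1.29 ± 0.0051. The small SD of the latter hides wide differences within runs. Its arrays read -0.75 and -1.84 in run 1 and -1.67 and -0.91 in run 2. Without the run 1 array with GSNO in channel 1 ftnA was at -1.004, and without the other run 1 array at -2.40. The rest of the 12 lowest were ydiH at -1.44 ± 0.53, ynfF, an anaerobic selenate or sulfoxide reductase subunit, at -1.37 ± 0.40, rpmG of the ribosome at -1.27 ± 0.16, pyrL, the leader peptide of pyrBI, at -1.24 ± 0.011, and bcp, a thiol peroxidase, at -1.14 ± 0.53. The arrays of pyrL likewise spread from -0.64 to -1.84 despite its small SD. Adjusted p-values of the 12 lowest ran from 0.00131 for yobF to 0.0467 for bcp. All were below 0 on all 4 arrays, as the rule that picked them required.

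**Figure D1:**
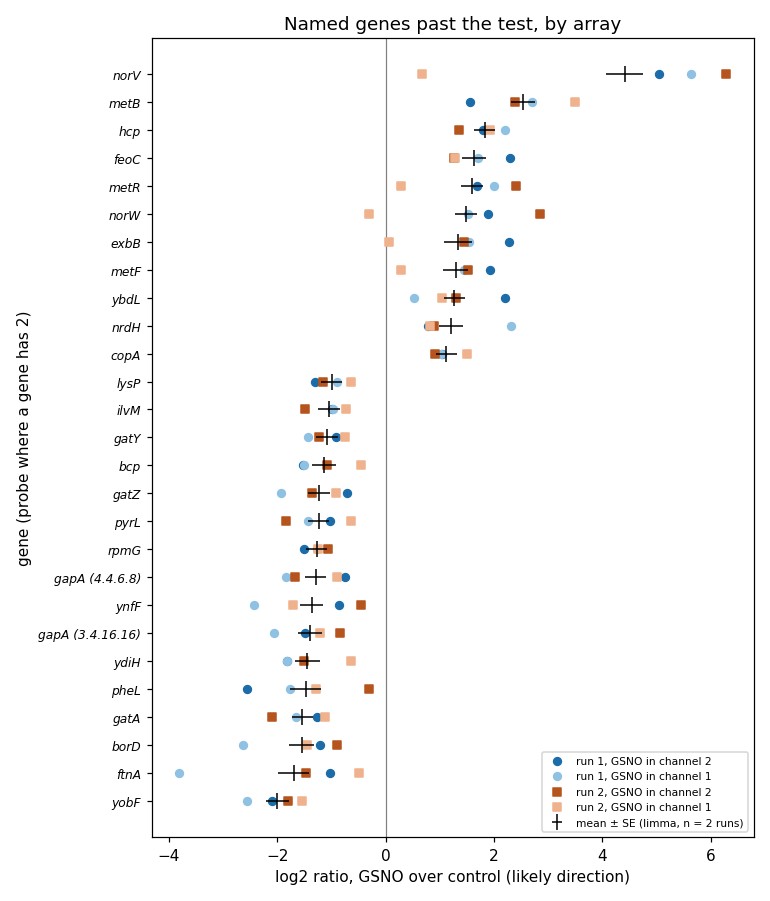
Log2 ratios (x axis, GSNO over control, likely direction) of the named genes past the limma test, 1 row per probe (y axis); points are the 4 arrays, coloured by run and dye orientation, and the cross is the mean with its limma standard error (n = 2 runs). The run 2 array with GSNO in channel 1 lies at 0.68 for norV and -0.32 for norW, far below the other 3 arrays, and at 3.50 for metB, above them.

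At an unadjusted p under 0.05, 247 probes were higher and 353 lower. By size alone, 9 probes were 2-fold or more higher in both runs and 11 were 2-fold or more lower, against 1 that passed 2-fold in both runs with opposite signs. At 1.5-fold the counts were 41, 78 and 24, at 2-fold on channel 2 arrays 38, 69 and 22, on channel 1 arrays 89, 26 and 11, and on all 4 arrays 4, 4 and 24. Across probes, which are not independent replicates, the dye-averaged ratios of the 2 runs correlated with Pearson's r = 0.34 and Spearman's rho = 0.27.

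The calls depend on how the 4 arrays are combined. The arrays with GSNO in channel 2 alone gave 4 higher and 9 lower probes, with norV and norW among the 4, and those with GSNO in channel 1 alone gave 0 and 0 (411 and 423 at an unadjusted p under 0.05). With the 4 arrays taken as independent limma called 0 and 0 both with a dye term (171 and 265 unadjusted) and, in a reading added after seeing the data, without it (104 and 182 unadjusted), so the dye term alone does not account for that loss. With a dye term and the run as a fixed block it called metB alone (1 and 0). In other readings added after seeing the data, leaving out each array in turn gave 0 and 0 without the channel 1 array of run 2 (119 and 182 unadjusted), without its channel 2 array (307 and 286 unadjusted) and without the channel 2 array of run 1 (104 and 226 unadjusted), and 19 and 40 without the channel 1 array of run 1, 17 of the 30 calls among them. Channel 1 arrays multiplied by -1 gave 0 higher and 31 lower. Averaged over a run, those values are the dye component, so its 31 calls, all in 1 direction, stand beside the 30 of the mean. Named probes alone gave 37 and 83. With the channel 1 arrays turned, 17 of the 30 calls kept their sign and none was called. With the run as a random block on the 4 arrays 21 of the 30 calls were kept, and exbB, metF, norW, nrdH, bcp, ftnA, pheL, ynfF and an unnamed probe did not pass. The arrays of a run correlated at -0.53 in that fit, which narrows the standard error of their mean, so the calls it kept are no independent check. With each array centred on its median 18 were kept, and exbB, metF, nrdH, copA, bcp, ftnA, pheL, gatY, lysP, ilvM, a gapA probe and an unnamed probe did not pass.

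**Figure D2:**
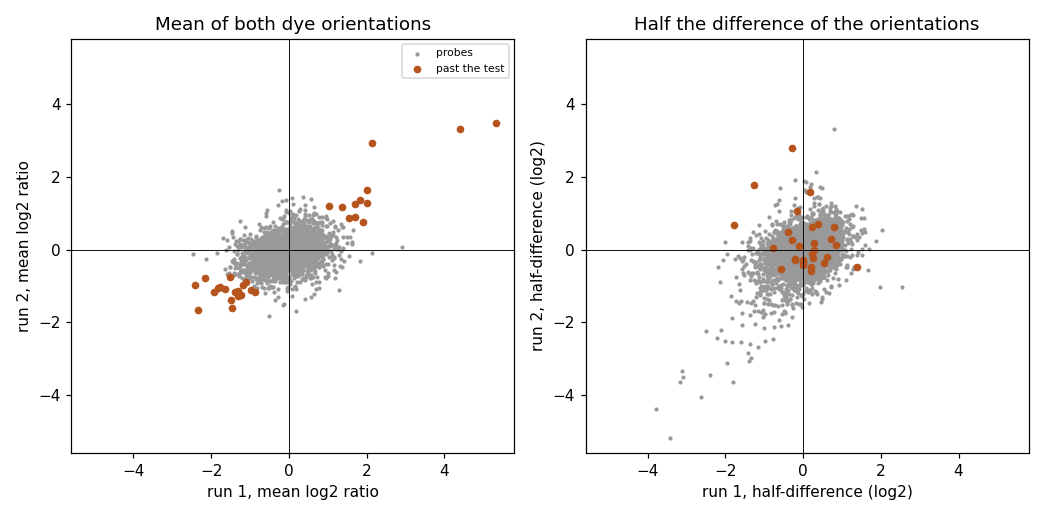
Run 1 (x axis) against run 2 (y axis) in log2 units for the 4608 probes, as the mean of both dye orientations (left) and as the dye component, the difference of the orientations divided by 2 (right); orange points are the 30 probes past the test. The runs correlate at 0.34 in the mean and at 0.43 in the dye component.

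Of the 24 gene lists, 3 stood higher and 7 lower than other probes by camera with a preset correlation. One of the 3 is nitric oxide detoxification, whose direction is no finding, as it holds the 6 genes that set the sign. With an estimated correlation none did, and the adjusted p was 0.552 for each of those 10 except ATP synthase (0.554). With 2 runs that form of camera has 1 residual degree of freedom. It found a simulated list shifted by 0.5 log2 in 0 of 20 sets, against 20 with the preset correlation. Its misses therefore do not show that correlation within the lists ended the calls. The simulated genes were independent, so the preset form was not tested on lists whose members move together. Against the preset 0.01, the estimated correlation was 0.56 for ATP synthase. For the other lists that passed it ran from -0.053 (glycerol) to 0.053 (ribosomal proteins). With 1 residual degree of freedom this estimate reflects only the direction in which each member differed between the 2 runs. It therefore cannot show how strongly the members of a list move together, and small values do not mean that they are independent. Fry, which asks whether a list's members move one way on balance or, in its other form, in either direction, passed none either way, with adjusted p = 0.263 for methionine in the first form and 0.0810 for ribosomal proteins in the second. On the channel 2 arrays alone 2 lists passed, methionine and ribosomal proteins. With each run of neighbouring members that share the first 3 letters of the symbol counted once, 8 did, all of the 10 except ATP synthase and the Fnr-activated genes.

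Methionine synthesis stood highest. Of its 15 genes 3 rose (metB, metR and metF), 12 did not pass and 13 had ratios above 0; adjusted over the list alone, 10 rose. The median was 0.67 (preset adjusted p = 7.78e-11; adjusted p = 0.552 with an estimated correlation). metA, the first enzyme of the pathway, stood at 0.91 ± 0.05 without passing (adjusted p = 0.0622). The list passed in each orientation alone, with medians of 0.82 and 0.53.

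Of 19 genes for nitric oxide detoxification, 3 rose (norV, hcp and norW) and 16 did not pass, with a median of 0.16 (preset adjusted p = 0.0146; adjusted p = 0.552 with an estimated correlation). These 3 are among the 6 members that set the sign of the ratios. Without those 6, in a reading added after seeing the data, the other 13 genes had a median of 0.057 and the list did not pass (preset adjusted p = 0.911, test down), with 7 of the 13 above 0. Adjusted over the list alone, 3 rose and nrfA, the periplasmic nitrite reductase that also reduces nitric oxide, fell (-0.73 ± 0.43; adjusted p = 0.143 over all probes). The flavohaemoglobin gene hmp was at 0.65 ± 1.01, with -0.07 in run 1 and 1.36 in run 2, hcr at 0.32 ± 0.78 and ytfE at 0.09 ± 0.09, none past the test. The list passed with the channel 1 arrays alone, and did not with the channel 2 arrays alone (median -0.04), with the run as a random block or without either run 2 array or the channel 1 array of run 1.

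The Fur list of iron acquisition had a median of 0.17 over 37 genes (preset adjusted p = 0.000792; adjusted p = 0.552 with an estimated correlation). exbB rose, and ftnA, which stores iron rather than acquiring it, fell. Adjusted over the list alone, 4 rose and 1 fell, the 4 being exbB, exbD and the ferrous iron uptake genes feoB (0.96 ± 0.26) and feoA (0.95 ± 0.02). Of its 39 probes, 32 were above 0. On the run 2 array with GSNO in channel 2, feoB was at -0.05.

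Ribosomal protein genes stood lower, with a median of -0.44 over 54 genes (preset adjusted p = 3.29e-19; adjusted p = 0.552 with an estimated correlation). Only rpmG fell over all probes, and 23 of the 57 probes fell adjusted over the list alone. Among those not past the test over all probes, rplS was at -1.17 ± 0.94, rpmB at -1.03 ± 0.55 and rpsG at -0.98 ± 0.24. The means of rplS and rpmB rest largely on 1 array each. On the run 2 array with GSNO in channel 1 rplS was at -3.64, against -0.03 to -0.71 on the others. On the run 1 array of that orientation rpmB was at -2.43, against -0.42 to -0.79 on the others. Just 4 probes of the list lay above 0, and the list passed in each orientation alone. The 9 ATP synthase genes were all below 0, with a median of -0.48. By camera the list had an adjusted p of 7.41e-05 with the preset correlation and 0.554 with an estimated one. These genes are neighbours that share their first 3 letters, so they are not 9 independent members. Counted once they form 1 unit, which did not pass (camera, preset correlation, adjusted p = 0.204). None passed over all probes, and 3 fell adjusted over the list alone: atpF (-0.74 ± 0.0028), atpH (-0.62 ± 0.13) and atpB (-0.58 ± 0.15). The arrays of atpF spread from -0.32 to -1.16, which its small SD between runs does not show. Those of atpH differed in sign in run 1, at 0.09 and -1.51.

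Among the biosynthetic and anaerobic lists, 4 stood lower, each at an adjusted p of 0.552 with an estimated correlation. Arginine synthesis (median -0.18 over 17 genes, preset adjusted p = 0.00273) had no gene past the test over all probes and 3 that fell adjusted over the list alone: the arginine transport genes artI (-0.95 ± 0.42) and artJ (-0.89 ± 0.16), and carA (-0.66 ± 0.25). Purine and pyrimidine synthesis (median -0.14 over 29 genes, preset adjusted p = 0.00273) likewise had 0 and 3, namely pyrI (-0.96 ± 0.23), pyrB (-0.76 ± 0.45) and purE (-0.69 ± 0.15). Glycerol uptake and catabolism (median -0.17 over 18 genes, preset adjusted p = 0.00665) had 0 and 4, including glpB (-0.95 ± 0.07) and glpC (-0.71 ± 0.04) of the anaerobic glycerol-3-phosphate dehydrogenase. The small SD of glpC hides run 1 arrays of opposite sign, at 0.26 and -1.63. Of 62 genes activated by Fnr, the regulator of anaerobic growth, ynfF fell and no other passed (median -0.10, preset adjusted p = 0.0146). Adjusted over the list alone 5 fell, among them frdD of fumarate reductase (-0.90 ± 0.43), and 1 rose, napH (0.90). The run 1 arrays of frdD differed in sign, at 0.43 and -1.64.

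The cold shock list, taken as a sign of sample handling, also stood lower, with a median of -0.29 over 11 genes (preset adjusted p = 0.00837; adjusted p = 0.552 with an estimated correlation). cspA at -1.002 ± 0.29 and cspE at -0.74 ± 0.13 fell adjusted over the list alone, and none passed over all probes. The run 1 arrays of cspE differed in sign, at 0.26 and -1.55. The cold shock list stood lower beside the ribosomal and ATP synthase lists.

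The other 14 lists did not pass. Of the branched-chain, aromatic and histidine list (median -0.03, adjusted p = 0.233) ilvM fell (-1.05 ± 0.09) and ilvC and ilvN (0.90 ± 0.38) lay above 0; adjusted over the list alone, 3 rose and 4 fell. Cysteine synthesis (median -0.10) and the aerobic respiration and TCA cycle list (median -0.10) each had an adjusted p of 0.0503, as did iron-sulfur cluster assembly (median 0.17), and none of their genes passed. Adjusted over the list alone, tcyJ (-0.87 ± 0.32) and cysJ (-0.85 ± 0.32) of the first and sdhC (-1.09 ± 0.63) of the second fell. On the run 2 array with GSNO in channel 2, cysJ was at 0.04 and sdhC at 0.11. In the OxyR list (median 0.10, adjusted p = 0.0835) no gene passed, and mntH (0.90 ± 0.51) and ahpC (0.65 ± 0.12) rose adjusted over the list alone. copA was the only called gene of the zinc and copper list (median 0.09, adjusted p = 0.520) and hcp of the nitrate and nitrite list (median 0.12, adjusted p = 0.374). No gene passed, either way of adjusting, in the lists of SoxRS (median 0.05, adjusted p = 0.913), SOS (0.09, adjusted p = 0.702), RpoS stress (0.05, adjusted p = 0.675), heat shock (-0.03, adjusted p = 0.883), formate hydrogenlyase (-0.01, adjusted p = 0.520), flagella and chemotaxis (0.04, adjusted p = 0.938) and phage shock (-0.05, adjusted p = 0.938). Median and test differed in sign for flagella (test down) and phage shock (test up).

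**Figure D3:**
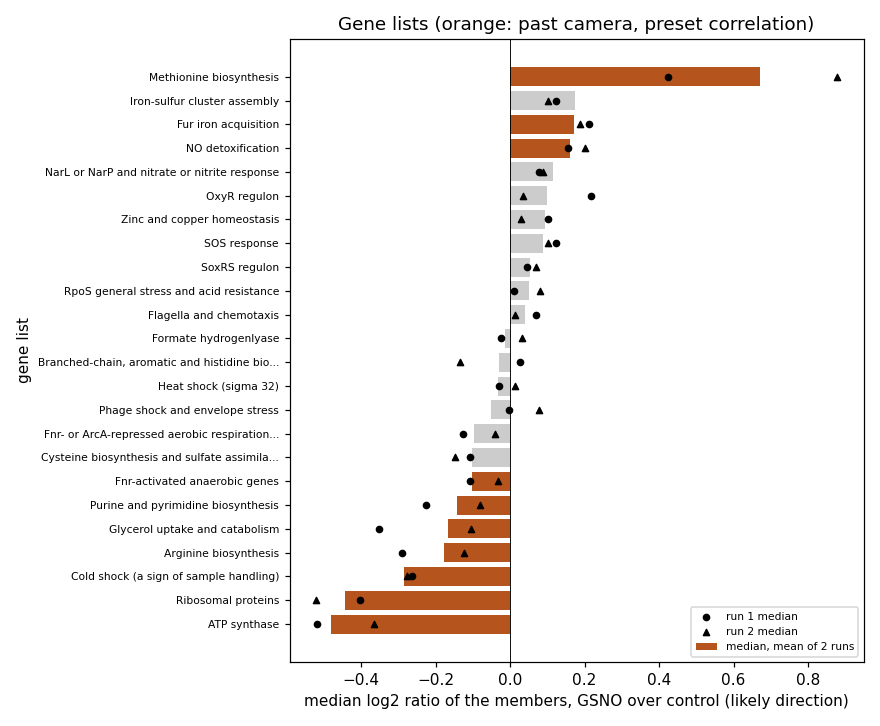
Median log2 ratio of each gene list's members (x axis, GSNO over control, likely direction; bars, mean of both runs) with the medians of run 1 (circles) and run 2 (triangles), for the 24 lists (y axis). Orange bars passed camera with the preset correlation, from 0.67 for methionine synthesis to -0.48 for ATP synthase.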

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

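Of the tests below, those of unturned values, of a repeating dye effect and of dye orientation alone were chosen after the result they explain had been seen. The test of the 50 raised probes was written before its medians were computed, but after values of single genes on that array had been seen.

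For 6 of the 107 named genes, both arrays of one dye orientation lay on one side of 0 and both of the other on the opposite side. The difference (channel 2 minus channel 1 arrays, log2) was 2.65 for pspF, 2.03 for pspB and 1.48 for hycB, and -2.76 for soxS, -2.24 for umuC and -1.65 for fliZ. They were picked out by sign, untested. Limma's dye difference, run for all probes, passed for none of the 6 (adjusted p from 0.0599 for pspF to 0.197 for hycB) and for 31 probes elsewhere. It is the same fit as that with the channel 1 arrays turned, so these are the 31 lower probes of that reading. None of the 6 was called as a response.

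An array and its dye swap did not agree across probes. Their correlation was near 0 in run 1 (r = -0.07), and only in run 2 did they run against each other (r = -0.40). If the deposited ratios had not been turned, the response would lie in the dye component, and operon-like neighbours would correlate more than other neighbours there. The excess was 0.015 in the dye component (permutation p = 0.72) and 0.27 in the mean (permutation p = 1e-04, the smallest that 10000 permutations can give), which argues against unturned values. Printing blocks accounted for 12.8% of the variance of the dye component. That is under the limit set beforehand, so they do not account for most of it, but they may account for a part. A dye effect of single probes that repeats between runs may account for the pattern, since the dye components of the 2 runs correlated at 0.43, and no biological explanation was tested because both arrays of a run carry the same RNA.

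On the run 2 array with GSNO in channel 1, norV stood at 0.68, norW at -0.32, metR at 0.29, metF at 0.28 and exbB at 0.06, against 1.44 to 6.29 on the other 3 arrays. Orientation alone does not account for this, as norV was at 5.64 on the run 1 array of that orientation. For a weaker response on that array, the median there of the 50 named probes highest on the other 3 arrays was 0.0865 times the like median of the run 1 array of that orientation, below the limit of 0.5 set beforehand, which by itself would have counted in its favour. After the result was seen the test was judged void, because each array's median is over its own 50 probes, so the ratio sets different genes against each other, and the like median was lower still (-0.92) on the run 2 array with GSNO in channel 2, where norV was at 6.29. Also, metB (3.50) and hcp (1.93) were not low on the array in question. The cause stays open, and the design gives no biological one.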

How the results depend on the processing

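The 4 arrays as independent without a dye term, channel 1 arrays turned, named probes alone, each array left out, symbols of the same first 3 letters counted once and the nitric oxide list without the 6 genes that set the sign were chosen after seeing the data. Against 12 higher and 18 lower probes, counts were 9 and 19 with the run as a random block (correlation of a run's arrays -0.53), 11 and 14 with robust eBayes, and 12 and 16 with a gene's probes averaged. They were 0 and 0 with the 4 arrays as independent, with a dye term or without, 1 and 0 with a dye term and the run as a fixed block, 4 and 9 on channel 2 arrays, 0 and 0 on channel 1 arrays, 0 and 0 without the channel 1 array of run 2, its channel 2 array or the channel 2 array of run 1, 19 and 40 without the channel 1 array of run 1, 0 and 31 with channel 1 arrays turned, 37 and 83 on named probes, 4 and 1 with treat and 34 and 67 at an adjusted p under 0.1. Lower counts were 10 with median centring, 28 with scaling and 30 with quantile normalization, and higher counts 8, 15 and 16. Of the 30 calls, the random block kept 21 and median centring 18. With all signs turned, 18 would be higher. Leaving out a run ends the test.

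Against 9 higher and 11 lower 2-fold probes, counts were 38 and 69 on channel 2 arrays, 89 and 26 on channel 1 arrays, 2 and 55 with channel 1 arrays turned, 41 and 78 at 1.5-fold, 4 and 4 on all 4 arrays, 15 higher without the channel 1 array of run 2, and 23 and 18 without its channel 2 array. Probes past 2-fold with opposite signs were 1, against 22 on channel 2 arrays, 11 on channel 1 arrays, 24 on all 4 arrays and 24 without the channel 1 array of run 2. With 1 run counts were 29 to 73 higher and 44 to 136 lower. The run correlation was 0.10 without the channel 1 array of run 2 and 0.23 to 0.49 elsewhere. Against 10 of the 24 lists, 2 passed on channel 2 arrays and 8 on channel 1 arrays, 0 with channel 1 arrays turned, 0 with an estimated correlation (1 residual degree of freedom), 3 without the channel 1 array of run 1 (arginine, methionine and ribosomal) and 3 with members of the same first 3 letters counted once wherever they lie (methionine, nitric oxide and ribosomal), which merges genes of many operons. Under the other settings 8 to 13 passed. Apart from fewer arrays, the cause was not tested.

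The nitric oxide list turned in its test without the 6 genes that set the sign (median 0.057), and in its median, without passing, on channel 2 arrays (-0.04). With the channel 1 arrays turned, signs turned for gatY (0.0081), ftnA (0.45), hcp (-0.24), nrdH (-0.36), copA (-0.14), gatZ (0.20), metB (-0.56), pheL (0.049), yobF (0.054), borD (0.50), gapA (0.23 and 0.080) and ynfF (0.71), and for the list medians of ATP synthase (0.23), Fnr-activated (0.021), Fur (-0.046), glycerol (0.27), nitric oxide (-0.12), purine and pyrimidine (0.12) and ribosomal genes (0.16), none of them past the test there. The missing-value filter and the intensity trend were not run. Signal over background is unknown.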

Other observations

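The tests here of fewer probes and of wider disagreement were written before their values were computed. Groups of neighbouring genes were looked at after the data were seen, with no test of their own, as means over members in run 1 and run 2.

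Several groups of neighbouring genes had all members on one side of 0 in the mean of the runs. Those given here were picked from many more groups. Others were also wholly on one side with small means, such as fruA, fruK and fruB (0.13) and sucABCD (-0.10). How many would be so by chance was not worked out, and neighbours that are not operon-like also correlated in the mean (r = 0.16). The feoABC group of ferrous iron uptake averaged 1.37 in run 1 and 0.99 in run 2, and metQ, metI and metN of methionine uptake 0.81 and 0.52. hemC, hemD, hemX and hemY of haem synthesis averaged 0.37 and 0.39. Below 0 lay the galactitol genes gatYZABCD, at -0.85 and -0.78 with 7 of 7 probes negative, pyrL, pyrB and pyrI at -1.15 and -0.83, and oppABCDF of oligopeptide uptake at -0.57 and -0.57. The sulfate assimilation genes cysH, cysI and cysJ stood at -0.57 and -0.49, and the fumarate reductase genes frdABCD at -0.36 and -0.54. For minC, minD and minE of division site placement the means were -0.31 and -0.80. The nrdHIEF group of ribonucleotide reduction averaged 0.65 and 0.50 with 3 of 4 members above 0, of which nrdH alone was called (1.21), and nrdE at -0.07.

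Of the leader peptide genes of amino acid and pyrimidine operons, looked at after their values were seen, pheL and pyrL fell. The genes trpL (-1.01 ± 0.46, adjusted p = 0.0622), leuL (-0.76 ± 0.17), thrL (-0.29 ± 0.53), ilvL (-0.19 ± 0.0082), ivbL (-0.17 ± 0.45) and hisL (-0.13 ± 0.93) did not pass, and differences between them were not tested. Within the branched-chain genes, ilvM fell while ilvB, ilvN and ilvC lay above 0.

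Leaving out the unnamed probes raised the calls from 30 to 120. Fewer tests alone do not account for this, since 0 of 100 random removals of as many named probes gave as many (13 to 99 calls). The runs disagreed 1.10 times as much at unnamed as at named probes by the median, which lies between the limits set beforehand against and for that explanation. By the 90th percentile, for which no limit was set, the ratio was 1.199. That leans towards wider disagreement there, which may or may not be the cause. The prior degrees of freedom rose from 10.5 to 21.2 on named probes, against 18.4 at most in the random removals. They measure how alike the spreads of the probes are, not how wide. In the removals the fewest calls (13) came at 7.15 and the most (99) at 18.1, so their rise is no separate evidence. The span of 13 to 99 calls shows how far the count moves with the probes that enter the shared spread. No biological explanation was tested.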
